A study of Mus musculus with 4 samples.

How the data were processed

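RNA abundance was measured in 4 cultures of C2C12 cells, a mouse myoblast line that can be made to form multinucleated muscle fibres in culture. Per the labels, all cultures carried a stably integrated pLKO.1 lentiviral vector. In 2 cultures it expressed a control short hairpin RNA (shRNA) and in the other two an shRNA against Sfmbt1. The labels disagree about the control hairpin, which one field calls scrambled and another names for luciferase, so it is called the control shRNA here. Per the labels' protocols, the cells were kept in serum-containing growth medium with puromycin, and RNA was purified with Trizol and a column that included a DNase step. Biotin-labelled cRNA was then hybridised to 1 Affymetrix mouse expression array per culture. The series text describes the cultures as independently grown biological replicates. Whether the 2 cultures of a group came from separate transductions was not established here. If they did not, the spread within a group covers variation between cultures only.

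The deposited values are linear probe set intensity values made by the authors with MAS5 in GCOS, per the submitters' processing notes, which give no versions. How the arrays were scaled to each other is not given in the sources used here. The values were used as deposited. The mean signal after trimming 2% from each end of the distribution was 353 and 376 on the control arrays and 346 and 381 on the knockdown arrays, so the arrays had not been set to 1 common trimmed mean over all probe sets. MAS5 subtracts mismatch signals and gives noisy values for dim probe sets, which is why a pseudocount and a filter were applied before testing.

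Of the 45101 probe sets on each array, 34945 were assigned to 1 gene by the array annotation, 932 to several genes and 9160 to none in that table, and 64 were controls. The annotation is an old release, so symbols were looked up by gene identifier in a RefSeq table of the GRCm38.p6 assembly. There 34741 of the 34945 probe sets matched, 204 kept the symbol of the annotation, and 0 symbols changed. That table was used for names and for the order of neighbouring genes, and no coordinates are given because the deposited values carry none. Every sample column was used.

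Signals were transformed as log2(signal + 16), and a fold change is on that scale, which understates the change of dim genes. Each of the 18194 named genes was represented by the probe set with the highest mean over the 4 arrays. Probe sets in the upper 60% of mean log2 signal were kept, a limit equal to a signal of 57.3, which left 12866 genes. Differences, knockdown minus control, were tested with limma 3.58.1 (lmFit, and eBayes with a trend of variance on mean level) in R 4.3.3. The Benjamini-Hochberg adjusted p had to lie under 0.05 for a gene to be called higher or lower. The within-group spread had 2 residual degrees of freedom, and the prior shared across genes added 13.8. A 2 against 2 comparison of a single gene by a two-sided exact permutation test cannot give a p under 0.333, which is why the model across genes was used. The number of arrays limits the precision.

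Background on each array was taken as the 95th percentile of 27 bacterial control probe sets. Where a gene lay in that range on both arrays of a group, its fold is given as a bound, the mean log2 signal of the brighter group against the background limit of each array of the dimmer group. Where only 1 of the arrays lay in that range, the fold is also given with that array's signal put at its background limit.

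Before the data were examined, 25 gene lists were fixed, with 1103 symbols written, of which 1099 matched a gene (98 through a synonym). Each list was tested, two-sided, with limma's camera with a preset correlation between genes of 0.01, with camera with an estimated correlation, and with fry. Camera asks whether a list moved relative to other genes, and fry whether its members moved on balance in 1 direction. Fry's mixed test asks whether members changed in either direction. Fry was run without the trend of variance on mean level that camera and the gene tests used, so its results are not on the same footing for dim genes. The p-values were adjusted over the 25 lists. Counts of members are given over all genes tested and adjusted over the list alone.

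Genes are named by a rule that was also fixed before the data were examined. It takes the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups of arrays do not overlap, passing over gene models without an assigned name. It also takes the 3 members with the smallest p of each muscle list and the 2 such members of each other list. Genes named beyond this rule were chosen after their values were seen, mostly so that short groups of calls are named in full.

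The steps were tested on simulated data for this comparison of 2 against 2 arrays. In 20 runs over 12866 genes, 200 genes were given known changes. The test called 61.05% of the genes changed by 1 log2 unit and 86.95% of those changed by 2 log2 units, and 4.39% of the calls were false. A list shifted by 0.5 log2 units was called by camera in 20 of 20 runs, and 3 of 480 unshifted lists were called. The simulated genes were drawn independently of each other, so these rates do not cover correlation between genes. Their spreads came from the fitted prior of the same model that then tested them. A share of false calls near the threshold was thus built in, and the rates do not cover departures of the real arrays from that model. On the real arrays the estimated correlation was 0.48 in the cell cycle list, 0.47 in the cholesterol list and 0.78 in oxidative phosphorylation.

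The alternatives tried were quantile normalization, median centring, pseudocounts of 1 and 64, no filter, an upper 40% filter, no variance trend, leaving out probe sets shared between transcripts, testing every probe set past the filter, the replicate number as a block, leaving out each array in turn, and an adjusted p threshold of 0.1. Where an array was left out, 1 group had a lone array, and the spread came from the other group and the shared prior. Passing the threshold in such a fit is therefore weak support. Probe sets of several genes were left out of the gene tests.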

Results

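RNA levels were compared between C2C12 mouse myoblasts carrying an shRNA against Sfmbt1 and C2C12 myoblasts carrying a control shRNA, with 2 independently grown cultures in each group and 1 array per culture. Sfmbt1 encodes a chromatin protein with MBT repeats. The comparison asks which genes differ in myoblasts when Sfmbt1 is knocked down. The median signal over all probe sets but the 64 controls was 97.8 and 102.7 on the control arrays and 92.8 and 101.1 on the knockdown arrays. Background, set by bacterial control probe sets, was 49.1 and 53.2 on the control arrays and 69.3 and 42.9 on the knockdown arrays. Again without the 64 controls, probe sets above background made up 65.0% and 64.3% in the control and 56.2% and 67.6% in the knockdown, so knockdown replicate 1 had the lowest share. The log2 difference between the 3' and 5' probe sets, a sign of RNA integrity, lay between -0.32 and -0.29 for Gapdh and between -0.01 and 0.18 for actin. For the transferrin receptor it was 1.16 and 1.65 on the control arrays and 1.51 and 1.58 on the knockdown arrays. Across genes, which are not independent replicates, log2 signals correlated at r = 0.975 between the control arrays, at r = 0.974 between the knockdown arrays and at r = 0.964 to 0.966 between arrays of different groups. The median absolute log2 difference was 0.178 and 0.208 within groups and 0.224 to 0.259 between them.

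Sfmbt1 itself had a lower signal in the knockdown in all 5 of its probe sets, with no overlap between the groups in any of them, which chance alone gives in 33.3% of probe sets in either direction. The largest drop among the 4 not in the background range throughout was in probe set 1422894, from 259.8 ± 25.6 in the control to 45.3 ± 41.4 in the knockdown (SD, n = 2 each), but 1 of the 2 knockdown arrays lay in the background range, so the level is a bound, at most 22.6% of the control with background in its place. This probe set passed when every probe set past the filter was tested (adjusted p = 0.0219 over 22893 probe sets), but not without the filter (adjusted p = 0.165 over 34945). In probe set 1422893 the signal was 260.9 ± 43.3 in the control and 114.1 ± 35.2 in the knockdown, 43.7% of the control (adjusted p = 0.0594). Probe sets 1429749 and 1455412 stood at 67.7% and 69.2% of the control, with adjusted p = 0.333 and 0.339. In probe set 1443853 all 4 arrays lay in the background range. The gene test used probe set 1429749, the brightest of them, and there Sfmbt1 did not pass (log2 -0.54, SE 0.25, adjusted p = 0.316).

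**Figure D1:**
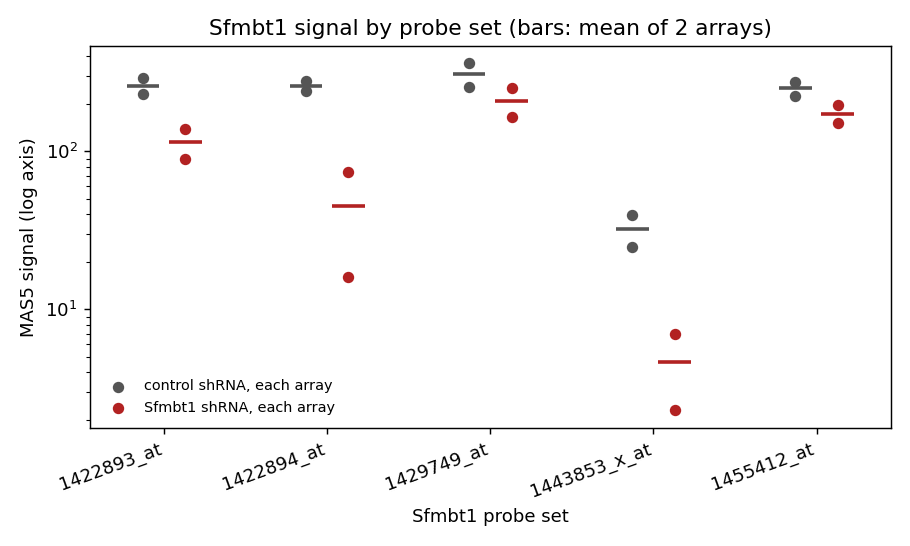
Signal of each Sfmbt1 probe set (horizontal axis) on each array, on a logarithmic vertical axis of MAS5 signal, with points for single arrays and bars for the mean of 2 arrays per group. Both knockdown points lie below both control points in all 5 probe sets, and the mean of probe set 1422894 is 45.3 against 259.8, with 1 of its knockdown points in the background range.

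Genes of the contractile apparatus and myogenin rose when Sfmbt1 was knocked down, while the acetylcholine receptor subunit gene Chrnd and the transcription factor gene Sp4 fell. Of 12866 genes tested, 185 were higher and 207 lower in the knockdown, and 63 of the higher and 46 of the lower changed by at least 2-fold. The higher genes started from a median control signal of 537.3 and the lower genes from 1335. All 392 had non-overlapping groups, which a call from 2 arrays per group nearly requires, so this adds no support. Without the variance trend limma called 0 genes at the adjusted threshold and 1501 at an unadjusted p under 0.05, against 1933 with the trend, and without the filter on dim probe sets it called 23 higher and 32 lower. Centring each array on its median gave 339 higher and 218 lower, so the share of higher genes went from 47.2% to 60.9%. Leaving out knockdown replicate 1 gave 407 higher and 264 lower, leaving out knockdown replicate 2 gave 167 higher and 450 lower, and leaving out control replicate 2 gave 212 higher and 128 lower.

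The 8 called genes with the highest fitted log2 differences were Tnni1, Myl1, Usp2, Tnnt1, Mylpf, Myog, Tnnc2 and Myh3. Myog encodes myogenin, a transcription factor of muscle differentiation, and went from a signal of 319 ± 32.3 to 1745 ± 124 (SD, n = 2 each; log2 2.40, SE 0.15, adjusted p = 4.83e-07). Tnni1, the slow skeletal troponin I, rose from 62.5 ± 45.3 to 673 ± 17.7 (log2 3.26, SE 0.32, adjusted p = 3.56e-05), and the fast myosin light chain gene Myl1 from 246 ± 161 to 1670 ± 55.7 (log2 2.84, SE 0.29, adjusted p = 3.70e-05). Mylpf, which encodes the fast regulatory myosin light chain, and Myh3, the embryonic myosin heavy chain, rose by 2.54 and 2.30 log2 units. The troponin genes Tnnt1 and Tnnc2 rose by 2.60 (SE 0.42) and 2.38 (SE 0.28) log2 units. In Tnni1 and Tnnt1 1 of the 2 control arrays lay in the background range, and with background in its place they were at least 7.87-fold and 4.34-fold higher. The sizes depend on the control arrays: without control replicate 1 the log2 differences were 3.89 for Tnni1, 3.46 for Tnnt1 and 2.16 for Myl1. Without control replicate 2 they were 2.64, 1.73 and 3.51. A pseudocount of 64 gave 2.59 for Tnni1 and 1.90 for Tnnt1. Usp2, which encodes a deubiquitinating enzyme, lay in the background range in both control arrays and was at least 4.52-fold higher in the knockdown (adjusted p = 5.36e-04).

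The 8 called genes with the lowest fitted log2 differences were Sp4, Chrnd, Mmp23, Acsl6, Adcy5, Pitpnm2os1, Cacng2 and Arhgap27, an order that rests in part on signals in the background range. Sp4, a zinc finger transcription factor gene, went from 236 ± 66.5 to 8.65 ± 1.77, in the background range of both knockdown arrays, and was at least 3.49-fold lower (adjusted p = 0.0012). Chrnd, the delta subunit of the muscle acetylcholine receptor, was at least 2.88-fold lower (adjusted p = 0.0083), Mmp23 and Arhgap27 at least 2.34-fold lower and the antisense transcript Pitpnm2os1 at least 2.53-fold lower. The adenylate cyclase gene Adcy5 fell by 1.93 log2 units (SE 0.30, adjusted p = 0.0019), the acyl-CoA synthetase gene Acsl6 by 1.93 (SE 0.49, adjusted p = 0.0411) and Cacng2 by 1.73 (SE 0.37, adjusted p = 0.0170). In these last 3 genes 1 of the 2 knockdown arrays lay in the background range, and with background in its place they were at least 3.42-fold, 2.23-fold and 2.97-fold lower. None of these 16 genes had another tested probe set. Without control replicate 1 the calls of Acsl6 (adjusted p = 0.0746), Arhgap27 (0.495), Cacng2 (0.299), Chrnd (0.136), Mmp23 (0.129) and Pitpnm2os1 (0.0896) were lost. Without control replicate 2 those of Acsl6 (0.0579), Mmp23 (0.124) and Pitpnm2os1 (0.109) were lost, and without knockdown replicate 1 that of Acsl6 (log2 -1.14, adjusted p = 0.0624), whose difference was -2.73 without knockdown replicate 2 and -1.24 with a pseudocount of 64. Quantile normalization ended the calls of Acsl6 (0.0890), Arhgap27 (0.0783) and Cacng2 (0.0523), and those of Acsl6 and Arhgap27 also ended with median centring (0.0780 and 0.0716), a pseudocount of 1 (0.0626 and 0.0559), every probe set (0.0684 and 0.0631) and the replicate number as a block (0.0678 and 0.0706). Arhgap27 did not pass without probe sets shared between transcripts either (0.0558).

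Sarcomere genes rose as a group. Of 34 tested members, out of 53 on the array, 14 rose and 0 fell over all genes tested (16 and 0 adjusted over the list alone), and 28 had a positive difference. The mean difference was 1.04 log2 units and the median 0.88. Besides the troponin and myosin genes above, the cardiac and skeletal alpha-actin genes Actc1 and Acta1 rose by 2.14 (SE 0.15) and 1.70 (SE 0.16) log2 units, and the cardiac and slow troponin C gene Tnnc1 rose from 306 ± 4.03 to 977 ± 25.95. The list moved relative to other genes in camera (adjusted p = 2.64e-18 with the preset correlation), and the adjusted p was 0.22 with an estimated correlation. The estimate was -0.025, under the preset 0.01, and that version rests on 2 residual degrees of freedom, where a pass is hard to reach. In fry, the rotation test of the list on its own, the adjusted p was 0.0070. For Myl4, an embryonic and atrial light chain gene that rose by 1.67 log2 units, another tested probe set gave -1.15.

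**Figure D2:**
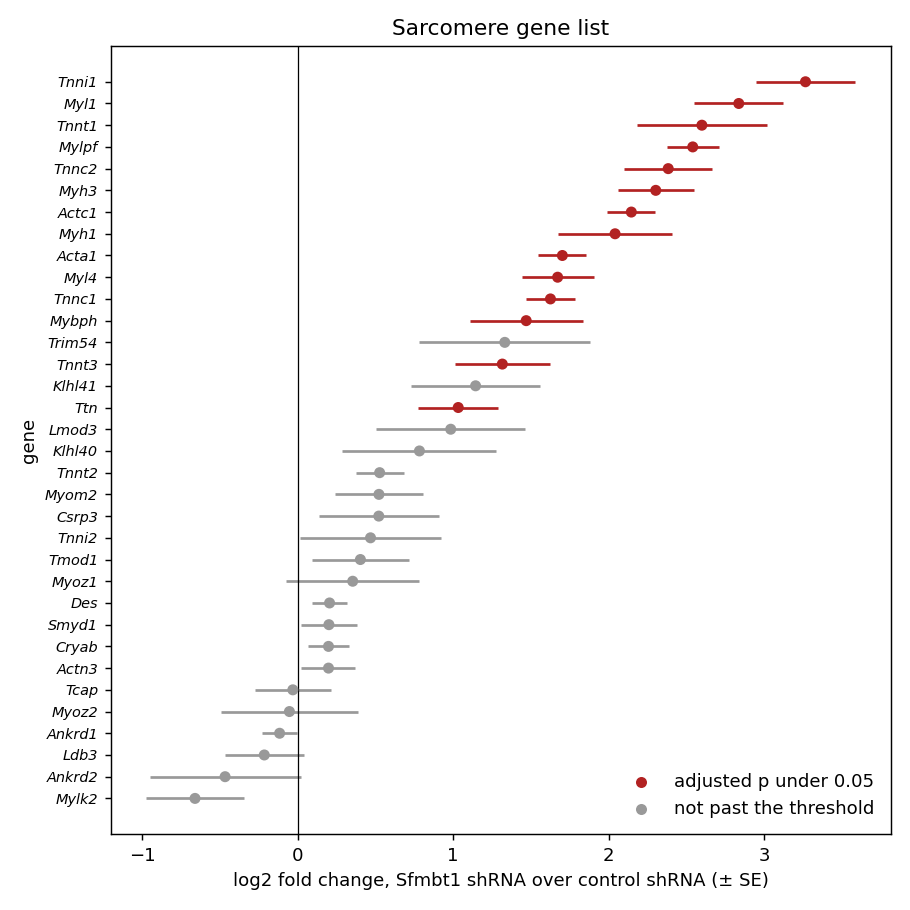
Log2 fold change of each of the 34 tested sarcomere genes (horizontal axis, knockdown over control, bars show the standard error of the fit from 2 arrays per group), with genes under an adjusted p of 0.05 in red. The 14 red genes all lie to the right of 0, from Ttn to Tnni1, and 6 of the others lie to the left of 0.

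Genes of excitation-contraction coupling and muscle energy metabolism went both ways. Of 27 tested members 2 rose and 3 fell (7 and 3 adjusted over the list alone). Sgca, which encodes alpha-sarcoglycan, rose by 2.17 log2 units (SE 0.31, adjusted p = 9.15e-04), at least 4.26-fold with background in place of the 1 control array in that range, and Art1, a muscle ADP-ribosyltransferase gene, by 1.81 (SE 0.30). Jph2, a junctophilin that ties the sarcoplasmic reticulum to the plasma membrane, fell by 1.102 (SE 0.15, adjusted p = 7.76e-04) and a second probe set of it fell by 1.15, while the muscle enolase gene Eno3 fell by 0.72 (SE 0.12, adjusted p = 0.0024). Chrnd was the remaining gene that fell, and without control replicate 1 its adjusted p was 0.136. The list did not move as a whole (mean 0.17, camera adjusted p = 0.35). In fry's mixed test, which 14 of the 25 lists passed, its adjusted p was 4.90e-04.

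Among 28 tested myogenic regulators 3 rose and 1 fell (3 and 4 adjusted over the list alone). Besides Myog, Msc rose by 1.54 log2 units (SE 0.22, adjusted p = 9.15e-04); it encodes musculin, a basic helix-loop-helix repressor. The cyclin-dependent kinase inhibitor gene Cdkn1a rose from 1877 to 2778 (log2 0.56, SE 0.13, adjusted p = 0.0224), with 1.24 in another probe set, and the zinc finger gene Klf5 fell by 0.50 (SE 0.13, adjusted p = 0.0440), with -0.15 in another. Myod1 was 3512 in the control and 2844 in the knockdown (log2 -0.31, SE 0.13, adjusted p = 0.289), and Myf5 565 and 477 (log2 -0.23, adjusted p = 0.597). The mean of the list was 0.07, its median -0.07 and the direction in camera down (adjusted p = 0.88), while fry gave up. Cdkn1a did not pass without control replicate 1 (adjusted p = 0.0608) or control replicate 2 (0.125), and Klf5 did not pass without control replicate 1 (0.160), control replicate 2 (0.204) or knockdown replicate 1 (0.104), or with every probe set (0.0631).

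Of 33 tested genes of myoblast fusion and adhesion 2 rose and 1 fell (2 and 2 adjusted over the list alone). Mymk, which encodes the fusion protein myomaker, rose from 98.7 to 312 (log2 1.51, SE 0.25, adjusted p = 0.0031), and Npnt, which encodes the matrix protein nephronectin, rose by 0.73 (SE 0.14, adjusted p = 0.0098), with 0.03 to 0.70 in 4 other probe sets. The chemokine receptor gene Cxcr4 fell by 0.71 (SE 0.15, adjusted p = 0.0173). The list did not move as a whole (mean -0.002, camera adjusted p = 0.63). Without control replicate 1 Npnt (adjusted p = 0.1001) and Cxcr4 (0.0600) did not pass, and without control replicate 2 Cxcr4 did not (0.0688).

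Cell cycle genes were slightly lower as a group, with 0 of 65 members higher, 2 lower (0 and 2 adjusted over the list alone) and 15 with a positive difference. The mean was -0.13 log2 units and camera gave an adjusted p of 3.71e-04 with the preset correlation, against an adjusted p of 0.97 with an estimated correlation and 0.80 in fry. The mitotic kinesin gene Kif11 fell by 0.72 (SE 0.14, adjusted p = 0.0122) and the cyclin E1 gene Ccne1 by 0.73 (SE 0.16, adjusted p = 0.0218). Without knockdown replicate 1 the list did not pass (mean -0.05, adjusted p = 0.0695). Kif11 did not pass without control replicate 1 (0.0660) nor Ccne1 without control replicate 2 (0.231) or without probe sets shared between transcripts (log2 -0.60, 0.110).

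In the list of cholesterol and fatty acid synthesis 1 of 26 members fell, 0 rose (1 and 0 adjusted over the list alone) and 6 had a positive difference. The gene that fell was Elovl6, a fatty acid elongase rather than an enzyme of sterol synthesis, from 2294 to 907 (log2 -1.32, SE 0.13, adjusted p = 3.56e-05), with -1.15 and -0.05 in its other probe sets. The next member by p, the sterol desaturase gene Sc5d, differed by -0.36 (adjusted p = 0.254). The list mean was -0.16, with a camera adjusted p of 0.0215 under the preset correlation, an adjusted p of 0.97 with an estimated correlation and 0.80 in fry. Without knockdown replicate 1 the list did not pass (mean -0.06, adjusted p = 0.148), and without the variance trend its adjusted p was 0.107.

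Extracellular matrix genes changed in both directions, 7 of 48 tested members higher and 5 lower (17 and 10 adjusted over the list alone). Col1a1, the alpha 1 chain of type I collagen, rose from 313 to 1254 (log2 1.96, SE 0.16, adjusted p = 9.00e-06), the matricellular growth factor gene Ccn2 from 1370 to 2924 (log2 1.08, SE 0.14, adjusted p = 2.63e-04) and the versican gene Vcan by 0.88. The membrane-type metalloproteinase gene Mmp14 fell by 0.87 (-1.75 and -1.29 in other probe sets), the thrombospondin genes Thbs2 and Thbs1 by 0.85 and 0.51, the laminin gene Lamc1 by 0.74 (-2.71 in another probe set) and Mgp by 0.47. The list as a whole did not pass (mean 0.13, camera adjusted p = 0.22), and its mean was 0.20 without control replicate 2. In fry's mixed test, which 14 of the 25 lists passed, its adjusted p was 0.0031. Without control replicate 2 Thbs1 (0.280), Lamc1 (0.0740) and Mgp (0.231) did not pass, and Mgp also did not without control replicate 1 (0.135) or knockdown replicate 1 (0.0805). With every probe set Thbs1 (0.0519) and Mgp (0.0596) did not pass.

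Of 51 tested genes for partners of Sfmbt1, Polycomb complexes and the LSD1 complex 0 rose and 4 fell (0 and 4 adjusted over the list alone). Bmi1, a core protein of Polycomb repressive complex 1, went from 1668 to 672 (log2 -1.29, SE 0.14, adjusted p = 5.85e-05), with -1.61 in a second probe set. Tfdp1, the dimerisation partner of E2F factors, fell by 0.91 (SE 0.13, adjusted p = 8.30e-04), Max, a partner of MYC-family factors, by 0.97 and the Polycomb-like gene Mtf2 by 0.81. Kdm1a, which encodes LSD1, was 1861 in the control and 1978 in the knockdown (log2 0.09, SE 0.13, adjusted p = 0.823). The list did not move as a whole (mean -0.09, camera adjusted p = 0.33), and without control replicate 2 Mtf2 did not pass (0.0568).

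All 7 tested genes of replication-dependent histones, of 10 on the array, had a positive difference, and 1 rose and 0 fell (1 and 0 adjusted over the list alone). That was H1f2, a linker histone gene, with 0.97 log2 units (SE 0.15, adjusted p = 0.0017), and H3c7 differed by 0.69 (adjusted p = 0.340). The list mean was 0.33 (camera adjusted p = 0.16). Of 24 tested imprinted genes 2 rose and 0 fell (4 and 0 adjusted over the list alone). They were the zinc finger genes Plagl1, by 1.93 (SE 0.29, adjusted p = 0.0013), and Peg3, by 0.62 (SE 0.12, adjusted p = 0.0099). The imprinted list had a mean of 0.15 (camera adjusted p = 0.21), passed without knockdown replicate 2 (0.0074) and with the upper 40% filter (0.0197), and Peg3 did not pass without control replicate 1 (0.0614).

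Of 24 tested inflammation genes 0 rose and 3 fell (1 and 3 adjusted over the list alone). The cytokine gene Il33 fell by 1.18 log2 units (SE 0.23, adjusted p = 0.0090), and the chemokine genes Ccl2 and Cxcl5 by 0.77 (SE 0.15, adjusted p = 0.0124) and 0.70 (SE 0.15, adjusted p = 0.0153). Among 28 tested p53 targets 2 rose and 1 fell (2 and 1 adjusted over the list alone). Cdkn1a and the cyclin G1 gene Ccng1, the latter by 0.52, rose, and Ei24 fell by 1.28 (SE 0.15, adjusted p = 1.82e-04). The camera adjusted p was 0.35 for inflammation (mean -0.10) and 0.91 for p53 targets, whose mean was -0.03 and median 0.05. Without control replicate 2 Il33 (0.0712), Ccl2 (0.0700), Cxcl5 (0.0568), Ccng1 (0.0516) and Cdkn1a (0.125) did not pass. Without control replicate 1 Cxcl5 (0.0558), Ccng1 (0.165) and Cdkn1a (0.0608) did not, nor did Ccng1 without knockdown replicate 2 (0.0781).

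In oxidative phosphorylation 1 of 51 tested members rose and 0 fell (0 and 0 adjusted over the list alone), and 38 had a positive difference. The ATP synthase subunit gene Atp5k rose by 0.53 log2 units (SE 0.13, adjusted p = 0.0414), and Ndufb7 differed by 0.46 (adjusted p = 0.108). The list mean was 0.08 (camera adjusted p = 0.084). It passed without control replicate 2 (0.0434) and without knockdown replicate 1 (4.02e-04, where Ndufb7 passed with 2.64e-04), with median centring (0.0032), with the replicate number as a block (0.0064) and with every probe set (0.0480). Without knockdown replicate 2 its mean was -0.04 (0.927), and its adjusted p was 0.97 with an estimated correlation and 0.89 in fry. Ndufb7 also passed with median centring (0.0495), the upper 40% filter (0.0212) and the block (0.0346). Atp5k did not pass without control replicate 1 (0.218), knockdown replicate 2 (0.202) or probe sets shared between transcripts (0.194), or with every probe set (0.0755). Of 24 tested targets of Notch, TGF-beta, BMP and Wnt signalling 1 rose and 0 fell (1 and 0 adjusted over the list alone), the Notch ligand gene Jag1 by 1.34 (SE 0.28, adjusted p = 0.0144), with 0.24 in another probe set. Id1, a target of BMP signalling, differed by -0.36 (adjusted p = 0.169), and the camera adjusted p of that list was 0.63.

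For interferon response (30 tested), germline (6), Hox (17), unfolded protein and heat shock (41), hypoxia and glycolysis (29) and epithelial genes (20), 0 members rose or fell over all genes tested, and at an unadjusted p under 0.05 limma counted 1, 0, 0, 10, 6 and 4 in that order. Adjusted over the list alone, limma called 1 gene in these lists, the epithelial junction gene Jup, which was lower (log2 -0.52, adjusted p = 0.0555 over all genes tested). The camera adjusted p was 0.91 for interferon, germline and unfolded protein genes, 0.63 for Hox and 0.52 for hypoxia and epithelial genes. The mean and median were 0.03 and -0.05 for interferon genes, 0.00 and 0.08 for germline genes, where camera gave down, and otherwise shared a sign. In fry's mixed test the germline list passed (adjusted p = 0.0017) with 0 members at an unadjusted p under 0.05, so a pass there need not mean that single members changed. Members with the smallest p were Bst2 (1.11) and Ifi204 (0.81), Tdrkh (-0.69) and Dppa3 (0.52), Hoxa10 (0.27) and Hoxa11 (0.19), Pdia6 (-0.45) and Atf3 (0.83), P4ha1 (0.54) and Egln3 (-0.48), and Pkp2 (-0.48) after Jup, all as log2 differences with adjusted p from 0.0555 to 0.673. In Bst2, Ifi204 and Dppa3 1 control array lay in the background range. Bst2 was 0.87 with background in its place, 0.44 without control replicate 2 and 1.78 without control replicate 1. Without single arrays some of them passed: Atf3 (6.66e-04) and P4ha1 (0.0181) without control replicate 2, and Bst2 (0.0141) without control replicate 1. Jup (0.0241) and Pdia6 (0.0197) passed without knockdown replicate 1, and Egln3 (0.0064), P4ha1 (0.0244) and Atf3 (0.0059) without knockdown replicate 2. With the upper 40% filter Atf3 (0.0182), Egln3 (0.0479), Jup (0.0198), P4ha1 (0.0197) and Pdia6 (0.0359) passed, with median centring Jup (0.0474) and P4ha1 (0.0466), with the replicate number as a block Jup (0.0362) and Pdia6 (0.0231), and with quantile normalization Jup (0.0361). The epithelial list passed without control replicate 2 (0.0434), while its mean was 0.05 without control replicate 1 (0.786) and 0.05 without knockdown replicate 1 (0.655), against -0.08 with all arrays.

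Markers of other cell types showed no shift as lists. Of 16 tested fibroblast and smooth muscle markers 0 rose and 3 fell (1 and 3 adjusted over the list alone). The smooth muscle actin gene Actg2 fell by 0.73 log2 units (SE 0.15, adjusted p = 0.0120), the actin-binding protein gene Tagln by 0.65 (SE 0.14, adjusted p = 0.0173) and the receptor gene Pdgfrb by 0.58 (SE 0.15, adjusted p = 0.0499). The mean of that list was -0.04, its median 0.02 and its camera adjusted p 0.52. Without control replicate 2 Tagln (0.128) and Pdgfrb (0.342) did not pass, and Pdgfrb also did not without control replicate 1 (0.0539) or knockdown replicate 2 (0.0729). Pdgfrb did not pass with median centring (0.0524), a pseudocount of 1 (0.0543), every probe set (0.0703) or without probe sets shared between transcripts (0.0526) either. Among adipocyte (12 tested), macrophage and leukocyte (11), endothelial and neural (16) and osteoblast and chondrocyte markers (9), 0 rose or fell over all genes, and adjusted over the list alone 1 osteoblast and chondrocyte marker was higher and 1 lower. At an unadjusted p under 0.05 limma counted 3, 0, 3 and 2. Their camera adjusted p were 0.87, 0.39, 0.37 and 0.91, and the osteoblast and chondrocyte list had a mean of 0.05 and a median of -0.05. The members with the smallest p were Cebpa (-0.51) and Car3 (0.38), Cd14 (-0.36) and Cd79a (-1.03), Sox10 (-0.88) and Egfl7 (-0.65), and Matn3 (1.05) and Sox9 (-0.53). In Cd79a 1 knockdown array lay in the background range, and with background in its place the difference was -0.42. Without single arrays Cd79a lay between -1.63 and -0.43 and Sox10 between -1.51 and -0.24. Without control replicate 2 Sox10 (0.0104), Matn3 (0.0126) and the endothelial and neural list (0.0434) passed, as did Sox10 without knockdown replicate 1 (7.79e-05) and Sox9 without knockdown replicate 2 (0.0092).

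**Figure D3:**
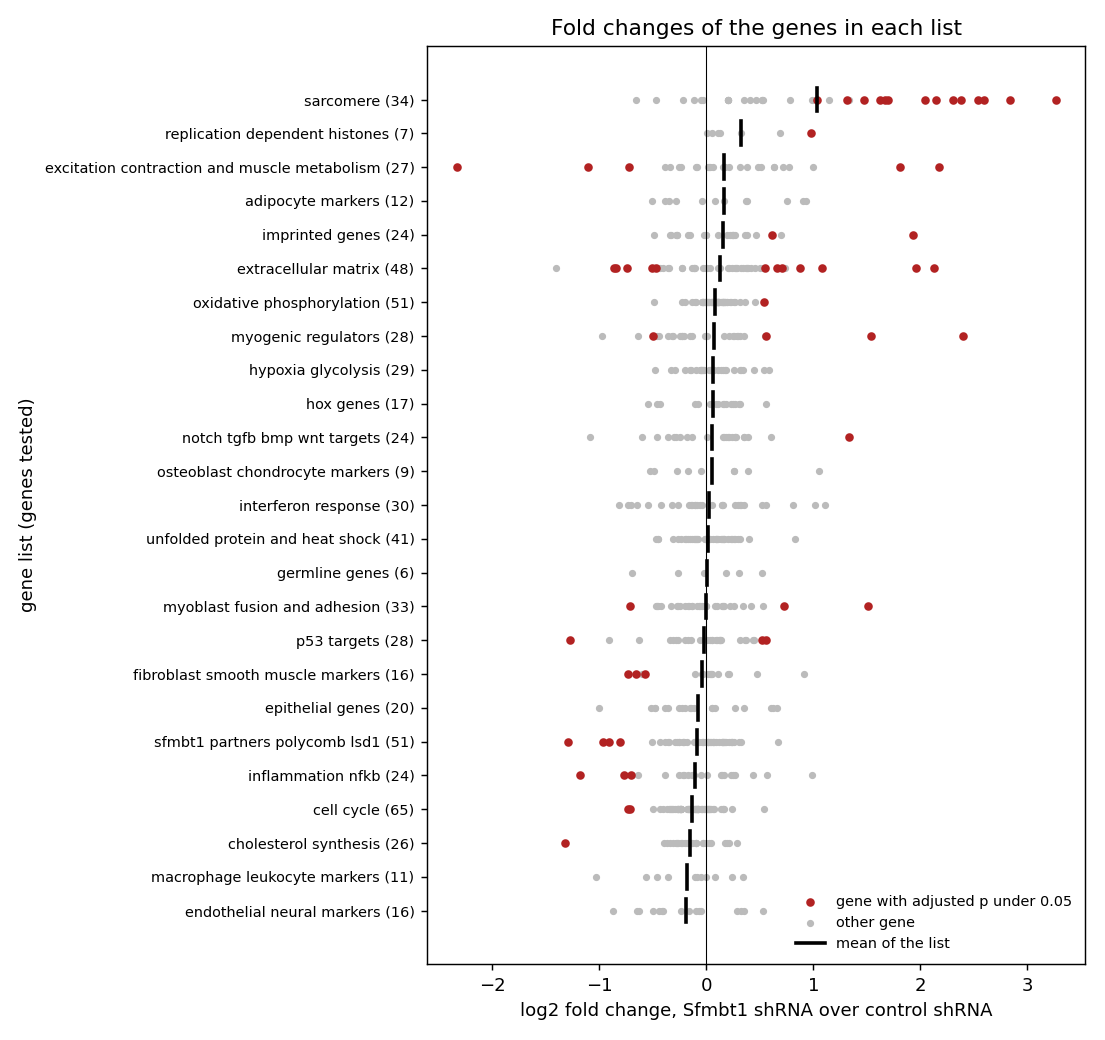
Log2 fold change (horizontal axis, knockdown over control, 2 arrays each) of every tested gene in each of the 25 lists, with the number tested in brackets; points are genes, red where the adjusted p is under 0.05, and black bars are list means. The sarcomere mean of 1.04 stands apart from the others, which lie between -0.19 and 0.33.

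Of the 25 lists, 3 passed in camera with the preset correlation (sarcomere, cell cycle and cholesterol synthesis), 0 passed with an estimated correlation and 1, sarcomere, passed in fry. With an estimated correlation camera rests on 2 residual degrees of freedom, so the 0 there does not by itself show that correlation undid the lists. In fry's mixed test, run without the variance trend, 14 passed.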

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

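2 signals lay outside the genes compared: a repeat-sequence control on the array, and probe sets to which the annotation assigns no gene. Of the tests in this part, those of scaling, of signals near background, of the share of differentiated cells, of the spiked controls, of the other splits of the arrays and of the share of called genes in extreme windows were chosen after the result was seen.

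The control probe set for the mouse B1 repeat, a short interspersed element present in many transcripts, was higher in the knockdown, 10501 ± 1534 against 16985 ± 3303 (SD, n = 2 each), by 0.69 log2 units (SE 0.15, limma adjusted p = 0.0472 over 27059 probe sets). The B2 repeat controls differed by -0.10 (adjusted p = 0.731) and 0.40 (adjusted p = 0.241). Genomic DNA or unspliced RNA in the labelled material cannot be told apart from a change of transcripts: the median difference of 3519 probe sets without a gene was -0.056, but a trace could raise a repeat of many copies without moving these, a limit seen after the test was set, and a B2 control also lay above 0. A scaling or hybridization difference would lift the 18 spiked hybridization controls by a like amount, and their mean was 0.12 (SD 0.07), 17.5% of the B1 difference. A change of transcripts that carry B1 elements stays open beside it, as a hypothesis, and it was not tested.

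Among those 3519 tested probe sets without a gene in the annotation, 10 were higher and 17 lower in the knockdown.

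The rise of the sarcomere genes was weighed against 3 explanations. Scaling between arrays would shrink it under quantile normalization, where the mean shift was 1.07. Noise near background would confine it to dim genes, but the 12 members with a control signal of 200 or more had a mean shift of 1.09 (SE of the mean 0.30), with 11 positive and 6 called higher. A larger share of differentiated cells in the knockdown cultures cannot be told apart from more RNA per cell, because 0 members were called lower and bulk signals do not separate these; the list of excitation-contraction coupling and muscle metabolism, with 2 members higher and 3 lower, does not decide it. An effect of lower Sfmbt1 on muscle gene expression is therefore a hypothesis. It stays open beside a difference in culture state and an off-target effect of the hairpin. Both of these go with the groups and were not tested.

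The 392 called genes were weighed as a set. If noise of single probe sets gave the calls, other tested probe sets of the same genes would share the sign about as often as for genes not called (60.7%), but 323 of 376 did, or 85.9% (exact 95% interval 82.0 to 89.3). These 376 probe sets belong to 209 of the 392 genes, and the other called genes are not covered. The exact intervals here treat probe sets of 1 gene as independent, so they are too narrow where these go together. Of called genes with a control signal under 200, 45 higher and 5 lower, only 10 had another tested probe set, and 8 of those 12 probe sets shared the sign, or 66.7% (exact 95% interval 34.9 to 90.1) against 52.5% for dim genes not called, so probe set noise stays open for them. A gained or lost chromosome segment would gather calls in runs of neighbouring genes. Windows of 41 genes beyond the limit set by 1000 shuffles of gene order held 4 of the calls, or 1.02%. Only 7 of 11984 windows lay beyond that limit, so this share was bound to be small. Most calls thus lay outside such windows, but shorter segments would not show in a median of 41 genes. The most extreme window ran from Fbxo32 to Arc, with Fbxo32, Tmem65 and St3gal1 called lower. It deviated by 0.247 against a limit of 0.247 (permutation p = 0.05), so a lost segment there can be neither excluded nor shown. The 4 arrays can be split into 2 and 2 in 3 ways, and 1 of the 3, the real one, gave 392 genes while the highest other gave 0; 3 splits are too few for a share under 0.05.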

How the results depend on the processing

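The alternatives were all fixed before the data were examined. None turned the direction of a called list, of a called gene named here, or of a gene called both there and in the main fit. Genes that lost their call were not checked unless named. With every probe set tested, a gene counted as turned only if all its called probe sets had the other sign. Single probe sets did differ: of the other tested probe sets of called genes, 323 of 376 shared the sign. For genes this was largely fixed in advance. All 392 had non-overlapping groups, so neither leaving out 1 array nor another pseudocount could turn the sign of a probe set. The filter, the variance trend, the block and the threshold leave the difference of a probe set unchanged. Apart from leaving out arrays and from dropping the variance trend or the filter, each kept at least 295 of the 392 called genes. The counts moved most as follows. Without the filter 23 genes were higher and 32 lower, mostly through the fit: its p corrected over the filtered genes alone gave 89 calls, and the filtered fit corrected over all genes 305 (chosen after seeing the data). With the upper 40% filter there were 285 and 322; at an adjusted p under 0.1, 285 and 314. Without the variance trend limma called 0 and 0, and 1501 at an unadjusted p under 0.05; the cause was not tested. Median centring gave 339 higher, and testing every probe set gave 328 lower (cause not tested). Leaving out 1 array, which assumes that the lone array of its group varies like the other group, gave 143 to 407 higher and 128 to 450 lower.

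The cell cycle list had an adjusted p of 0.968 with an estimated correlation, 0.797 in fry and 9.98e-05 to 0.0695 without single arrays. The cholesterol list had 0.968, 0.797, 0.00156 to 0.148, and 0.107 without the variance trend. The sarcomere list had 0.224 with an estimated correlation (-0.025, tested on 2 residual degrees of freedom), and a mean shift of 0.81 to 1.20 over its alternatives. Of 396 list values under alternatives 378 stayed on their side of the threshold, 8 calls ended and 10 were gained; of 1322 such values of named genes 1116 stayed, 180 ended and 26 were gained. Of 69 named genes called in the main fit, 44 lost the call without the filter and all 69 without the variance trend. Sfmbt1 in the gene test lay between -0.82 and -0.26 without single arrays.

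The cultures are described as independent, and deviations of same-numbered arrays correlated at 0.01 across genes, a value that an offset common to all genes would not move. Replicate 2 had the higher median signal in both groups, 102.7 against 97.8 in the control and 101.1 against 92.8 in the knockdown. A tie through the replicate number therefore cannot be excluded. With the number as a replicate block 276 genes were higher and 270 lower, and 364 of the 392 were among them. Depth is limited by signal over background: 56.2% to 67.6% of probe sets lay above it, and folds of called genes named here are given as bounds too where a group had an array within it.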

Other observations

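Several called genes outside the lists, chosen after their values were seen, have known roles in muscle or its surroundings. Pdlim3, a Z-disc protein gene, rose from 170 ± 18.03 to 447 ± 36.1 (SD, n = 2 each; log2 1.31, SE 0.20, limma adjusted p = 0.0019), and Sspn, which encodes sarcospan of the dystrophin complex, rose from 165 ± 26.2 to 426 ± 60.9 (log2 1.29, SE 0.22, adjusted p = 0.0032), with 0.22 in another probe set. The secreted factor genes Pdgfc and Sfrp2 rose by 1.67 (SE 0.17) and 1.70 (SE 0.21) log2 units, with 0.77 in another probe set of Pdgfc. Against these, Myl9, the regulatory light chain of smooth muscle and non-muscle myosin, fell from 2191 ± 221 to 811 ± 101 (log2 -1.42, SE 0.15, adjusted p = 4.23e-05), so the myosin light chain genes named here went both ways.

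Genes with other functions also fell from high signals, likewise chosen after their values were seen. Grem1, which encodes a secreted BMP antagonist, fell from 3999 ± 537 to 1657 ± 153 (log2 -1.26, SE 0.14, adjusted p = 5.79e-05), and the monocarboxylate transporter gene Slc16a1 from 2905 ± 302 to 1184 ± 102 (log2 -1.28, SE 0.14, adjusted p = 5.16e-05). Macroh2a1, which encodes the histone variant macroH2A1, fell from 3412 ± 201 to 1550 ± 43.6 (log2 -1.13, SE 0.13, adjusted p = 7.91e-05). Without single arrays the differences lay between -1.40 and -1.12 for Grem1, -1.39 and -1.18 for Slc16a1, and -1.19 and -1.07 for Macroh2a1. They lay between 1.22 and 1.41 for Pdlim3, 1.15 and 1.44 for Sspn, and 1.56 and 1.78 for Pdgfc. For Sfrp2 they were 1.64 to 1.77 and for Myl9 -1.54 to -1.29. Without the variance trend none of these genes was called, and without the filter Pdlim3 and Sspn were not called.

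Host transcripts of small nucleolar RNAs were among the called genes: Gas5 rose by 0.82 log2 units, with -0.16 to 0.52 in 3 other probe sets, Snhg3 by 0.86 and Snhg8 by 0.68. A shared change of such hosts, a hypothesis formed from these genes, would lift the others too, and the mean of the 11 other tested Snhg genes was 0.075. They went both ways, from -0.46 (Snhg11, SE 0.36) to 0.41 (Snhg17, SE 0.22). A rise of the whole class by a like amount was thus not seen, while a smaller rise of some members stays open. This test was chosen before that mean was seen. Without knockdown replicate 2 Snhg3 (adjusted p = 0.0651) and Snhg8 (0.0553) did not pass, nor did Snhg3 with quantile normalization (0.0514), every probe set (0.0506) or the replicate number as a block (0.0587).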
